A study of Homo sapiens with 3 samples.

How the data were processed

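Polyadenylated RNA of 3 HEK293 libraries was sequenced: 1 control library and 2 libraries of partial KANK1-KO clones, 114 and 174. Per the series' design text, a plasmid carrying Cas9 and a guide placed just after the first start codon of KANK1 was transfected with a lipid reagent and the cells were cultured for 3 days. Per the labels' protocols, stranded libraries were built from total RNA and converted for MGI sequencers. The guide and its complement are given as 22 and 24 bases that are not each other's complement, and neither matched any of 206694 GENCODE release 29 transcripts. The target site was therefore not placed in the genome here, and the edited alleles were not analysed here.

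Per the submitters' processing notes, reads were handled with cutadapt 2.10, HISAT2 2.2.1 and Cuffdiff 2.2.1, with the build hg19; their settings and the gene annotation are not given in the sources used here. The authors deposited 1 table of FPKM per library, with 26237 gene symbols, and 2 tables of log2 ratios of clone to control. FPKM are scaled for transcript length and library size, so they are not counts, no count model was applied, and a value of exactly 0 can be a failed estimate. In each of them 28 rows carried a date in place of a symbol, as spreadsheets make of the septin and MARCH genes, and were left out, leaving 26209 symbols. The authors' deposited log2 ratio tables held 9296 rows each, of which 9286 equalled the log2 ratio of the deposited FPKM without a pseudocount within 1e-09. They covered 100% of the genes above 0 in all 3 libraries from A to N but only 46 of 6248 from P to Z, so only their KANK1 values were used.

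Depth was estimated from the FPKM that 1 fragment adds to transcripts of at least 1500 bases, assuming fragments of 200 bases. Relative depth from genes of at most 0.3 FPKM put the value of 1 fragment in clone 114 at 0.972 of that in the control, and in clone 174 at 0.960. The summed FPKM were 530251, 462950 and 492750 in the control, clone 114 and clone 174. Pearson correlations of log2(FPKM + 1) across genes were 0.989 for the control with clone 114, 0.987 for the control with clone 174 and 0.981 between the clones, and no gene above 1 FPKM in both libraries of a pair had equal values.

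Genes with a mean of at least 1 FPKM over the libraries (12577) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a trend and Benjamini-Hochberg adjustment at 0.05. A pseudocount of 1 FPKM understates the change of low genes. The fit had 1 residual degree of freedom, the difference between the clones, and a prior of 8.80 degrees of freedom, so the single control was assumed to vary like a clone. Whether the clones were separate cultures beyond their separate numbers is not stated, and p-values measure only the spread between these libraries. Tested on simulated data of 12577 genes in 20 runs, the fit recovered 6.5% of 2-fold, 67.5% of 4-fold, 90.6% of 8-fold and 95.9% of 32-fold changes, and 13.7% of its calls were false, above the nominal rate; the cause was not tested. This was 20.75 false calls per run, more than the 10 calls in the measured data, and the share holds only for runs with many simulated changes.

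Gene lists, named genes, tests and most alternatives were set before the data were examined. Of the 30 lists, those reported covered the KANK family, KANK1 partners, centriole duplication, pericentriolar material and appendages, mitosis, cytokinesis, G1/S, p53 targets, focal adhesion, extracellular matrix, epithelial and mesenchymal markers, YAP/TAZ, Wnt, immediate early, stress response, interferon, cholesterol, hypoxia and glycolysis, neuronal, kidney, ciliary, ribosomal protein, mitochondrially encoded, histone and reference genes, and markers of 4 other cell types. The mitochondrially encoded list matched 0 symbols. Lists with at least 3 tested genes were compared with all other genes by camera with a preset correlation of 0.01. This was repeated with an estimated correlation, which has 1 degree of freedom here and can hardly call any list. The same lists were also tested with fry, which tests a list by itself rather than against other genes. It too rests on the 1 residual degree of freedom of the fit. Named genes were the KANK family, the 10 highest and 10 lowest called genes moving alike in both clones by more than the clones differ, filled where fewer passed by the largest shared changes, up to 4 members per list, and the 10 highest and lowest between clones. Other members named in the text were chosen after their values were seen.

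Single clones were compared with the control without a test. List and chromosome medians were placed among 10000 random gene sets matched in 10 bins of expression, a step checked on simulated data. Intervals of chromosome medians are 95% binomial intervals over genes. Chance values for clones that share 1 control came from 100 simulations in which the control varied as much as a clone. Chromosomes and gene order were taken from the RefSeq table of GRCh38.p14 by symbol, without coordinates, for 12416 of the tested genes, and GC content and transcript length from GENCODE release 29 for 12348. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, leaving out duplicate symbols, quantile normalization, eBayes without a trend, each clone left out and camera with an estimated correlation. Added after the data were seen were leaving out genes listed at 0, scaling FPKM to the same sum, and subtracting each chromosome's median change.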

Results

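Messenger RNA was measured by sequencing in HEK293 cells, a line derived from human embryonic kidney that grows as an adherent culture. The series holds 3 libraries, 1 from unedited control cells and 2 from cell clones, numbered 114 and 174, in which KANK1 was partly knocked out with CRISPR/Cas9. KANK1 encodes a scaffold protein that links adhesion sites and the cell cortex to microtubules. The title of the series asks whether loss of part of the KANK1 dose is involved in centrosome defects. Values were deposited as FPKM (fragment counts scaled by transcript length and sequencing depth), without read counts. Genes at or above 1 FPKM numbered 12330 in the control, 12573 in clone 114 and 12434 in clone 174. The only replicates were the 2 clones, and p-values measure only the spread between them.

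KANK1, the edited gene, was listed at 4.49 FPKM in the control, 3.63 in clone 114 and 3.43 in clone 174. The log2 change of the clones against the control was -0.28 (SE 0.40), with -0.25 in clone 114 and -0.31 in clone 174, and it did not pass the limma test (adjusted p = 1.00). With FPKM scaled to the same sum in each library, the KANK1 change was -0.16. The authors' deposited table gave KANK1 log2 ratios of -0.31 for clone 114 and -0.39 for clone 174. At the depth estimated from the FPKM of 1 fragment, these values stand for about 356 to 403 fragments in the control, 295 to 334 in clone 114 and 284 to 321 in clone 174, depending on the transcript. The guide was placed just after the first start codon, so an edited transcript could still be counted, and the alleles of the clones were not analysed here. Among the paralogs, KANK2 was listed at 7.94 FPKM in the control, 14.8 in clone 114 and 8.92 in clone 174, with no call (adjusted p = 1.00). KANK3 was at 0.474 FPKM in the control, 0.967 in clone 114 and 0.954 in clone 174, below the level tested. KANK4 was listed at 0 in the control and at 0.212 FPKM or less in the clones. Of the KANK family list, 2 members were tested and 0 passed over all genes or adjusted over the list alone.

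The first comparison asked which genes differed between the 2 partial KANK1-KO clones and the control. FOS, a transcription factor gene induced within minutes by growth factors and stress, fell from 30.1 FPKM in the control to 4.25 in clone 114 and 3.39 in clone 174 (log2 change -2.70, SE 0.36, adjusted p = 0.0336). TP53I3, a p53-induced oxidoreductase gene, rose from 5.08 FPKM to 31.1 and 28.2 (log2 change 2.33, SE 0.33, adjusted p = 0.0498). RPL21, a ribosomal protein gene, was listed at 0.014 FPKM in the control and at 15.3 and 14.9 in the clones (adjusted p = 0.0025). Another such gene, RPL10, was at 499 FPKM in the control and 317 and 313 in the clones. The low RPL21 values may therefore be failed estimates rather than its expression. The other 7 called genes encode small nucleolar or Cajal body RNAs, which guide the modification of ribosomal and spliceosomal RNA. SNORA70 and SNORD22 were listed at 0 in the control, SNORA70 at 49.6 and 50.4 FPKM and SNORD22 at 29.9 and 30.6 FPKM in the clones. SCARNA22, SNORA40, SNORA61, SNORA71C and SNORD97 were listed at 0 in both clones and between 11.3 FPKM for SNORD97 and 32.2 FPKM for SCARNA22 in the control. The fragments behind these small RNA values were not estimated and may be few. The library preparation selects poly(A) tails, and whether these values stand for the mature small RNAs was not tested. Of 12577 genes tested with limma, 4 were thus called higher and 6 lower. An unadjusted limma p under 0.05 was reached by 218 genes, which is 1.73% of those tested. If no gene changed, a share of 0.05 would be reached, so small p-values were fewer than chance alone would give. Over 9 alternative settings, the adjusted p of FOS ranged from 0.00201 to 1.00 and that of TP53I3 from 0.00201 to 1.00, and each passed in 3. Leaving out duplicate symbols is among these 3, but it removed no gene and so repeated the reported fit. Setting clone 114 apart from the other libraries in the same way gave 18 calls and setting clone 174 apart gave 44, more than the 10 for the control.

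The remaining named genes had the largest changes shared by both clones without passing the threshold. SPARC, which encodes a matrix glycoprotein, was listed at 15.5 FPKM in the control, 54.8 in clone 114 and 54.2 in clone 174 (log2 change 1.75, adjusted p = 0.233). IAH1 was at 9.31 FPKM in the control, 33.3 and 39.5 in the clones, and SLC35D2 at 2.11, 9.41 and 9.61. HSPB8, a small heat shock protein gene, was at 1.32, 9.46 and 25.7 FPKM, CUTA at 1.32, 8.35 and 39.3, and TCN2, the gene of a vitamin B12 carrier, at 0.294, 4.28 and 3.98. On the lower side, EGR1, another immediate early transcription factor gene, was listed at 90.6 FPKM in the control, 13.6 in clone 114 and 4.33 in clone 174 (log2 change -3.38, SE 0.52, adjusted p = 0.0879). CALCB, a neuropeptide gene, was at 427 FPKM in the control, 40.8 in clone 114 and 0.0699 in clone 174 (adjusted p = 1.00), and it passed only where genes were required to have a mean of at least 5 FPKM. NSFP1, a pseudogene that shares sequence with NSF, was at 8.73, 0.742 and 0.588 FPKM, and SNORA62 at 6.55 FPKM in the control and 0 in both clones.

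**Figure D1:**
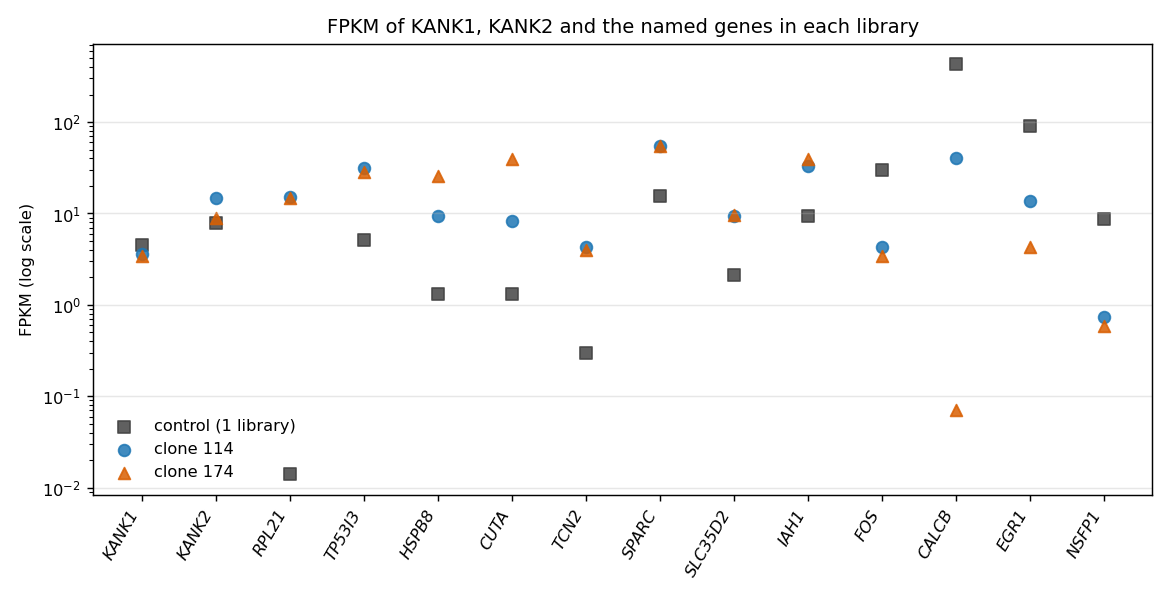
FPKM on a log scale (y axis) of KANK1, KANK2 and the named genes other than small RNA genes (x axis), with 1 point per library: the control (square), clone 114 (circle) and clone 174 (triangle). TP53I3 sits at 31.1 and 28.2 FPKM in the clones against 5.08 in the control, and FOS at 4.25 and 3.39 against 30.1, while the 3 points of KANK1 lie between 3.43 and 4.49.

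Among 30 gene lists fixed before the data were examined, 25 had enough tested genes for camera, which compares a list with all other genes. With an estimated correlation camera has 1 degree of freedom here, so those adjusted p-values cannot decide whether a list changed. By fry, which tests a list by itself, no list was called (lowest fry adjusted p = 0.801). The unadjusted fry p was 0.0712 for cholesterol synthesis, 0.0793 for p53 targets, 0.273 for immediate early genes and 0.351 for extracellular matrix. The list calls below thus rest on camera with the preset correlation alone. Immediate early genes fell as a group: 13 of 23 were lower in both clones and 2 higher, with a median log2 change of -0.36 (camera, adjusted p = 2.35e-05; adjusted p = 0.787 with an estimated correlation). FOS alone passed over all genes and 2 members, FOS and EGR1, adjusted over the list alone. KLF4 was at 12.4 FPKM in the control, 4.49 in clone 114 and 5.90 in clone 174, and FOSL1, against the list's direction, at 2.22, 5.53 and 4.28. Genes of cholesterol synthesis fell as well, with 15 of 23 lower in both clones and 0 higher (median log2 change -0.31, adjusted p = 1.52e-06; adjusted p = 0.787 with an estimated correlation). IDI1 was at 66.8, 37.8 and 38.8 FPKM, NSDHL at 66.1, 34.2 and 40.2, INSIG1 at 73.0, 31.0 and 45.1 and SQLE at 54.8, 35.5 and 25.9. No member of the cholesterol list passed by itself, over all genes or adjusted over the list alone. With FPKM scaled to the same sum in each library, an alternative chosen after the data were seen, both calls stayed but the medians were -0.22 for immediate early genes and -0.16 for cholesterol synthesis.

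The p53 target genes rose as a group, with 16 of 25 higher in both clones and 4 lower (median log2 change 0.20, adjusted p = 6.73e-05; adjusted p = 0.787 with an estimated correlation). Scaling to the same sum gave the p53 list a median of 0.34. TP53I3 was the 1 member past the threshold over all genes and also adjusted over the list alone. MDM2, which encodes the ubiquitin ligase of p53, was at 47.6 FPKM in the control, 76.3 in clone 114 and 78.1 in clone 174, GDF15 at 0.667, 2.18 and 1.40, and CDKN1A, the gene of a cyclin-dependent kinase inhibitor, at 71.0, 110 and 93.9. Extracellular matrix genes rose too, with 13 of 29 higher in both clones, 2 lower and 14 in opposite directions (median log2 change 0.26, or 0.34 in clone 114 and 0.12 in clone 174, adjusted p = 7.77e-05; adjusted p = 0.787 with an estimated correlation). The median was 0.16 at a mean of at least 5 FPKM and 0.36 with FPKM scaled to the same sum. In this list 0 members passed over all genes and 1, SPARC, adjusted over the list alone. COL4A2, a basement membrane collagen gene, was at 23.4, 48.3 and 47.0 FPKM and MMP2, a gelatinase gene, at 1.80, 6.98 and 3.83, whereas LOX, the collagen cross-linking enzyme gene, was at 9.11, 3.05 and 3.16.

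Another 4 lists fell with the preset correlation but lost the call under quantile normalization. The ranges over 9 alternatives given for them leave out the estimated correlation. The 1258 most abundant tested genes also lay lower, with a median log2 change of -0.24 in clone 114 and -0.13 in clone 174, against 0.02 and -0.04 for the other genes. Ribosomal protein genes were lower in both clones for 35 of 44 and higher for 1 (median log2 change -0.26, adjusted p = 6.73e-05; adjusted p = 0.787 with an estimated correlation), and quantile normalization gave a median of -0.02 (adjusted p = 0.559, against a range from 8.74e-07 to 0.559 over 9 alternatives). RPL37 was at 519 FPKM in the control, 255 in clone 114 and 302 in clone 174, RPS16 at 1872, 1344 and 1285 and RPLP0 at 1546, 1062 and 1110.3. RPS18 was at 6.72, 341 and 9.94, and its low values in the control and clone 174 may be failed estimates, as for RPL21. Hypoxia and glycolysis genes were lower in both clones for 17 of 28 (median log2 change -0.26, camera adjusted p = 0.00146, or 0.787 with an estimated correlation). Quantile normalization left the hypoxia median at -0.20 (camera adjusted p = 0.0764, with 1.35e-05 to 0.0764 over 9 alternatives). In that list NDRG1 was at 32.8, 13.9 and 23.9 FPKM, PGK1 at 544, 328 and 402, ENO1 at 1908, 1245 and 1361 and LDHA at 718, 537 and 509. Unfolded protein and amino acid stress genes were lower in both clones for 14 of 29 (median log2 change -0.24, camera adjusted p = 0.00583, or 0.806 with an estimated correlation). Quantile normalization moved the stress median to -0.13 (camera adjusted p = 0.0867, with 0.00116 to 0.0867 over 9 alternatives). Without it, the stress list had a median of -0.43 in clone 114 and -0.06 in clone 174, with SDF2L1 at 56.2, 37.3 and 37.4 FPKM and XBP1 at 51.7, 31.6 and 40.4. Common reference genes were lower in both clones for 10 of 19 (median log2 change -0.16, adjusted p = 0.0335; adjusted p = 0.787 with an estimated correlation), but their median turned to 0.043 after quantile normalization (adjusted p = 0.559, with 0.00116 to 0.559 over 9 alternatives), and SDHA was at 141, 72.4 and 84.4 FPKM. Without SDHA the reference list lost its call (adjusted p = 0.129). At a mean of at least 5 FPKM the stress list (camera adjusted p = 0.0780) and the reference list (camera adjusted p = 0.0837) lost theirs too. Their medians hardly moved, at -0.23 for the stress list and -0.16 for the reference list. Scaling to the same sum moved the medians to -0.11 for ribosomal proteins, -0.12 for hypoxia and glycolysis, -0.097 for the stress list and -0.0095 for reference genes. In these 4 lists 0 members passed over all genes or adjusted over the list alone. The called gene RPL21 is not a member of the ribosomal protein list.

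**Figure D2:**
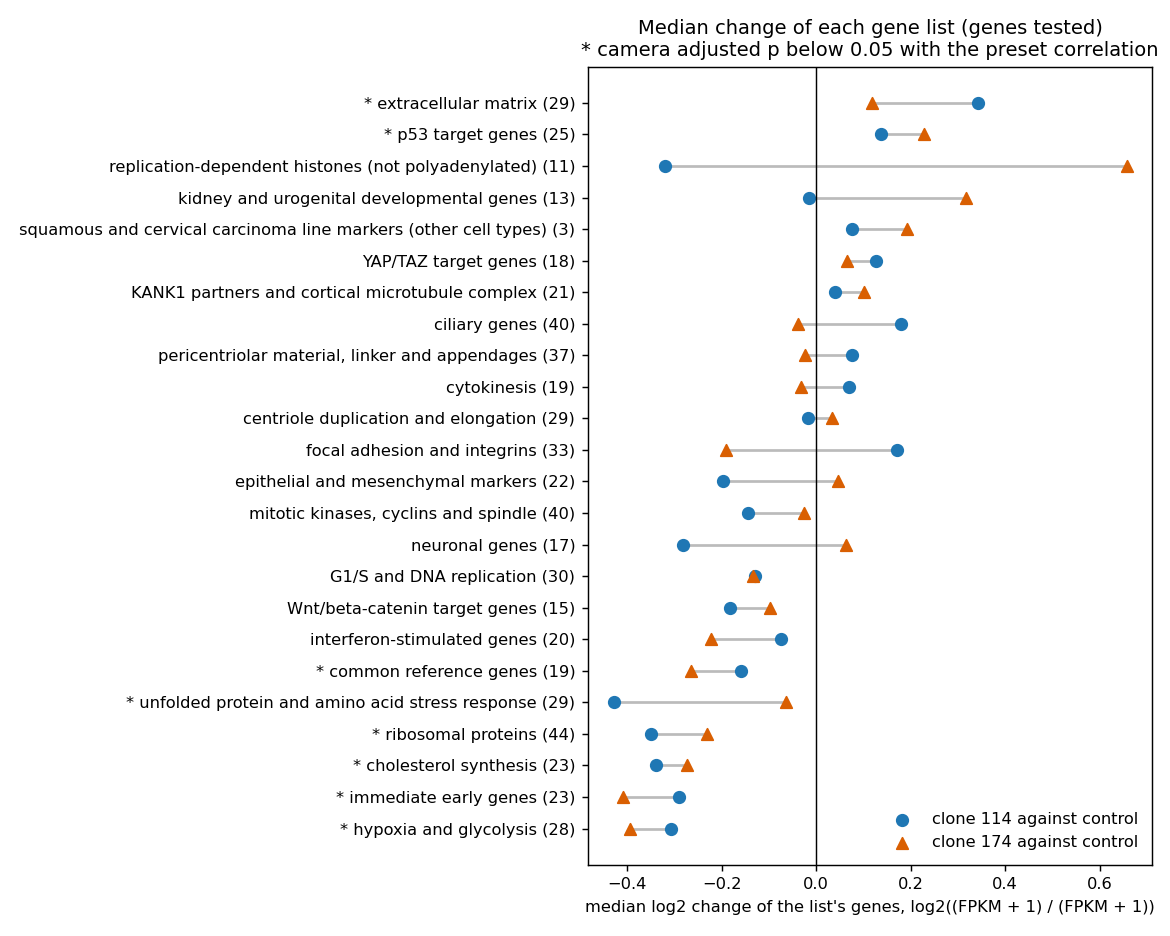
Median log2 change of the tested genes of each list (x axis, on the log2(FPKM + 1) scale) in clone 114 (circle) and clone 174 (triangle) against the control, with the number of genes tested in brackets. Asterisks mark the 8 lists called by camera with the preset correlation, and their points lie on the same side of 0 in both clones. With an estimated correlation, where camera has 1 degree of freedom and can hardly call a list, 0 kept the call.

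The question in the title directs attention to centrosome genes, and neither centrosome list was called. Of 29 genes of centriole duplication and elongation, 7 were higher and 9 lower in both clones (median log2 change -0.04, camera adjusted p = 0.995, although camera set the direction as up). PLK4, the kinase that starts centriole duplication, was at 12.8 FPKM in the control, 10.6 in clone 114 and 9.46 in clone 174, and CETN2 and CETN3, the centrin genes, at 73.6, 60.9 and 60.7 and at 45.1, 35.3 and 32.8. Of 37 genes of the pericentriolar material, the centriole linker and the appendages, 15 were higher and 12 lower (median log2 change 0.11, mean -0.01, camera direction up, adjusted p = 0.950), with CEP72 at 11.2, 6.85 and 7.40 FPKM and CCDC15 at 2.28, 4.17 and 3.64. Mitotic kinase, cyclin and spindle genes were lower for 19 of 40 and higher for 9 (median log2 change -0.09, adjusted p = 0.457), with CDC20 at 214, 160 and 148 FPKM and BIRC5 at 145, 82.0 and 111. Cytokinesis genes were higher for 6 of 19 and lower for 4 (median log2 change 0.00, adjusted p = 0.582), with VPS4B, the gene of an ATPase of membrane scission, at 29.8, 23.9 and 26.2 FPKM. Among 30 genes of G1/S transition and DNA replication, 10 were lower and 3 higher (median log2 change -0.08, adjusted p = 0.263; called after each chromosome's median was subtracted), with E2F1 at 58.7, 38.3 and 35.1 FPKM, CCND1 at 12.6, 4.12 and 8.01 and CDK6 at 5.32, 9.81 and 10.5. Ciliary genes were higher for 12 of 40 and lower for 5 (median log2 change 0.06, adjusted p = 0.176), with BBS2 at 17.1, 24.4 and 23.4 FPKM. In these 6 lists 0 members passed over all genes or adjusted over the list alone. In simulated data of the same size the test recovered 6.5% of 2-fold and 67.5% of 4-fold changes, so smaller changes in single centrosome genes would mostly go uncalled.

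Genes that act with KANK1 at the cell cortex were not called as a group either: 7 of 21 partner genes were higher and 3 lower in both clones (median log2 change 0.07, adjusted p = 0.583), with BAIAP2, the gene of an actin regulator, at 13.5 FPKM in the control, 8.71 in clone 114 and 10.4 in clone 174. Focal adhesion and integrin genes had a median log2 change of 0.17 in clone 114 and -0.19 in clone 174, with 9 of 33 higher and 5 lower in both (adjusted p = 0.447), and PARVB was at 3.70, 9.42 and 21.3 FPKM. Epithelial and mesenchymal markers were higher for 7 of 22 and lower for 8 (median log2 change -0.09, mean 0.04, camera direction up, adjusted p = 0.950). EPCAM, an epithelial adhesion gene, was at 6.35 FPKM in the control, 23 in clone 114 and 31.2 in clone 174 (adjusted p = 0.226), and it was the 1 member past the threshold adjusted over the list alone, against 0 over all genes. YAP/TAZ targets were higher for 6 of 18 and lower for 3 (adjusted p = 0.282), Wnt targets lower for 7 of 15 and higher for 3 (adjusted p = 0.457), and interferon-stimulated genes lower for 9 of 20 and higher for 5 (adjusted p = 0.430). The neuronal list had 4 of 17 genes lower and 2 higher (adjusted p = 0.974), and the kidney and urogenital list 5 of 13 higher and 4 lower (adjusted p = 0.234). Replication-dependent histone genes, whose transcripts lack the poly(A) tail that the library preparation selects, had medians of -0.32 in clone 114 and 0.66 in clone 174 (adjusted p = 0.759). Apart from EPCAM, 0 members of these 9 lists passed over all genes or adjusted over the list alone.

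Each clone was next set against the control by itself, which leaves no replicate and no test. On the log2(FPKM + 1) scale, 225 genes were at least 2-fold higher and 171 at least 2-fold lower in clone 114, and 243 and 204 in clone 174. With FPKM scaled to the same sum the counts were 357 higher and 110 lower in clone 114, and 286 and 153 in clone 174. Without that scaling, 42 were higher and 34 lower in both clones. Simulated unchanged clones shared 145 higher and 144.5 lower genes, under the assumption that the control varied as much as a clone. Independent lists of these sizes would share 4.35 and 2.77. The covariance of the clones' changes across genes was 0.0569, below the simulated range of 0.141 to 0.203. Their Pearson correlation across genes, which are not independent replicates, was 0.249 against a simulated mean of 0.497. The standard deviation across genes was 0.46 and 0.50 for the clones against the control but 0.59 between the clones. These values argue against the assumption, which limma also makes, so the simulated counts are no valid chance level for the shared genes. The immediate early list lay at percentile 0.01 of 10000 expression-matched random lists in clone 114 and at percentile 0 in clone 174, and the p53 list at percentiles 98.8 and 99.9. Cholesterol synthesis lay at percentiles 0.07 and 1.11, the extracellular matrix list at 100 and 97.0, and the ribosomal protein list at 1.06 and 4.97. Hypoxia and glycolysis genes lay at percentiles 0.32 and 0, whereas the unfolded protein and amino acid stress list lay at 0 in clone 114 and 60.6 in clone 174, and the common reference genes at 56.1 and 5.02. Centriole duplication genes lay at percentiles 30.8 and 81.6. Lists that were not called also reached extreme percentiles, such as focal adhesion at 99.6 and 3.55, ciliary genes at 99.2 in clone 114, neuronal genes at 0.22 in clone 114 and histones at 0.37 and 100.

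The clones differed from each other more than either differed from the control, with 279 genes at least 2-fold higher and 447 at least 2-fold lower in clone 174 than in clone 114 (241 and 572 with FPKM scaled to the same sum). SOX3, a transcription factor gene of neural progenitors, was at 1.27 FPKM in clone 114, 107 in clone 174 and 9.36 in the control. MGST1, a glutathione transferase gene, was at 0.333 FPKM in clone 114 and 32.6 in clone 174, TMEM47 at 0.356 and 31.8, NELL2 at 0.594 and 25.2, and HTATIP2 at 0.0490 and 14.1. In the other direction COL2A1, the collagen gene of cartilage, was at 93.6 FPKM in clone 114, 0.0504 in clone 174 and 16.8 in the control, and LCP1, an actin-bundling protein gene, at 46.3, 0.164 and 30.1. GAL, a neuropeptide gene, was at 36.0 FPKM in clone 114 and listed at 0 in clone 174. FAM213A was at 36.8 and 0.204 FPKM, COCH at 97.9 and 2.54 and CALCB at 40.8 and 0.0699. RPS18 was at 341 and 9.94, where the lower value may be a failed estimate. Small RNA genes filled the remaining places: SNORA43, SNORA65, SNORD94, SNORA34 and SNORA8 were listed at 0 in clone 114, and SNORA10, RNU6ATAC and SCARNA27 at 0 in clone 174.

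Expression also shifted by chromosome, in opposite directions in the clones for some chromosomes and in the same direction for others. Genes of chromosome 7 had a median log2 change of 0.38 in clone 114 (95% interval over genes 0.35 to 0.41) and -0.23 in clone 174 (-0.26 to -0.21). Chromosome 5 genes were lower in both clones, with medians of -0.41 in clone 114 and -0.18 in clone 174, and chromosome 14 genes had medians of -0.08 and -0.47. Chromosome 4 (-0.17 and -0.14) and chromosome 11 (0.06 and 0.17) also moved alike. Chromosome 3 (0.15 and -0.18), chromosome 10 (0.11 and -0.15) and chromosome 17 (-0.18 and 0.05) went opposite ways, as chromosome 7 did. Chromosome 18 lay at -0.30 in clone 114, chromosome 21 at -0.29 in clone 174, and chromosomes 2 and 12 at 0.24 and 0.21 in clone 174. For 12 of 23 chromosomes in clone 114 and 16 of 23 in clone 174 the median lay outside all 10000 expression-matched random gene sets. Chromosome membership accounted for 14.3% of the variance of changes between genes in clone 114 and 15.7% in clone 174, against at most 0.308% and 0.370% in 100 shuffles. Between the clones, chromosome 7 had a median of -0.62 (clone 174 against clone 114) and 15 of 23 chromosomes lay outside all random sets. Chromosome 9, which carries KANK1, had medians of -0.02 and 0.09. The latter was 0.17 after the trend with expression, GC content and transcript length was removed and all genes were centred on their median. The same step moved chromosome 19 in clone 174 from 0.02 to 0.15. Before it, the median of all tested genes in clone 174 was -0.05, so part of both moves is a shift common to all chromosomes. FOS lies on chromosome 14, EGR1 and SPARC on chromosome 5 and TP53I3 on chromosome 2. Subtracting each chromosome's median in each clone, an alternative chosen after the data were seen, left FOS at a log2 change of -2.42 and TP53I3 at 2.21 and ended both calls (adjusted p = 0.117 and 0.175, each with 0.00201 to 1.00 over 9 alternatives).

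**Figure D3:**
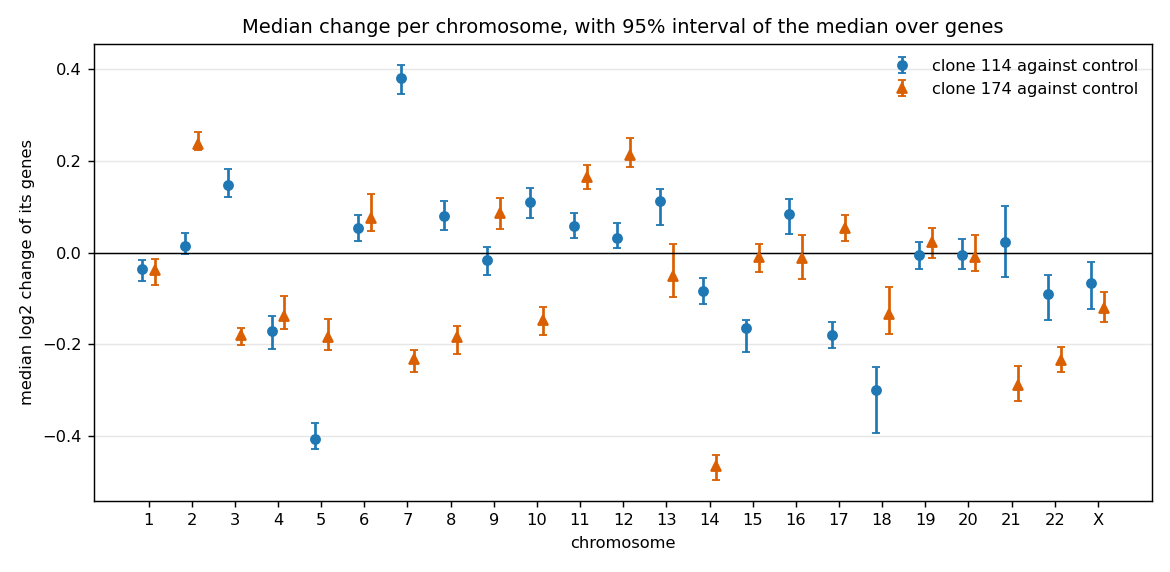
Median log2 change of the tested genes of each chromosome (y axis; x axis, chromosome) in clone 114 (circle) and clone 174 (triangle) against the control; bars are 95% intervals of the median over genes, not over replicates. Chromosome 7 lies at 0.38 in clone 114 and -0.23 in clone 174, and chromosome 14 at -0.08 and -0.47.

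**Figure D4:**
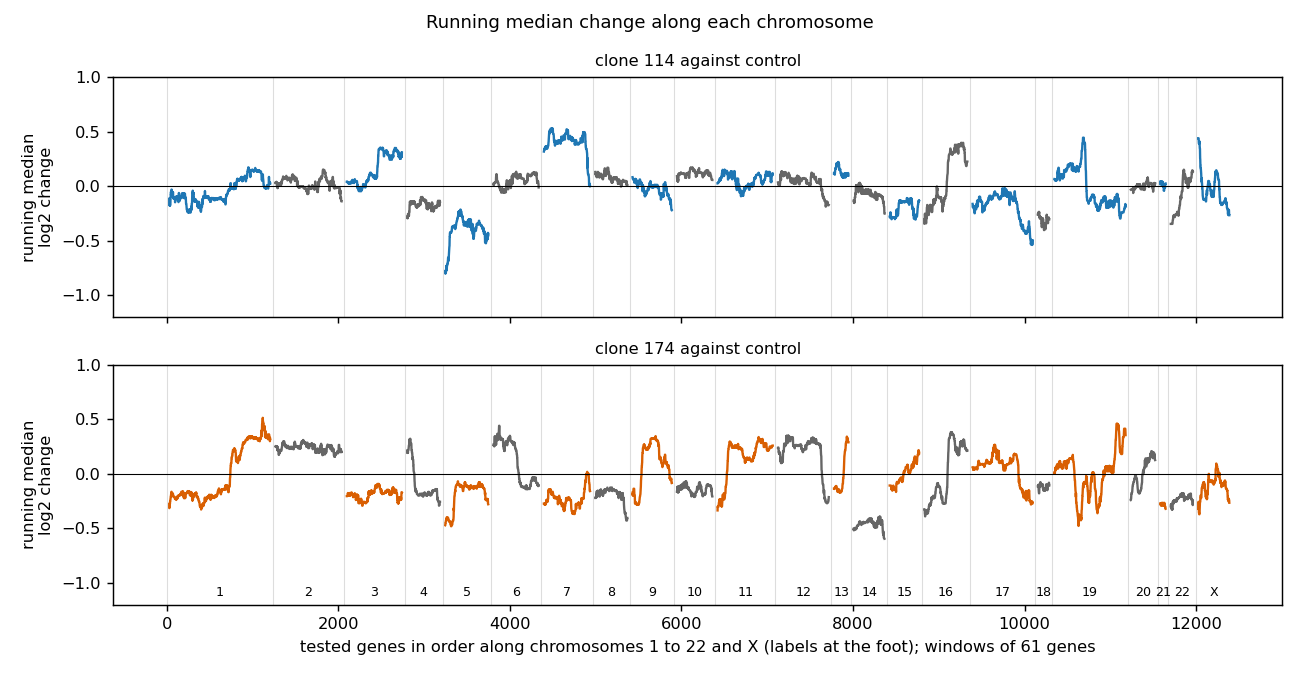
Running median log2 change over windows of 61 tested genes (y axis) in gene order along chromosomes 1 to 22 and X (x axis), for clone 114 (top) and clone 174 (bottom) against the control; colours alternate by chromosome. Values stay raised over nearly all of chromosome 7 in clone 114 and lowered over chromosome 14 in clone 174, where the chromosome medians were 0.38 and -0.47.

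Most markers of other cell types were below the level tested, and some were well expressed in all 3 libraries. Of the hepatocyte and gut markers only CDX2 was tested, a homeobox gene at 17.0 FPKM in the control, 12.4 in clone 114 and 5.27 in clone 174, while ALB, the albumin gene, reached at most 0.0299 FPKM. Among fibroblast markers COL1A1 was at 2.54, 2.43 and 4.22 FPKM and TWIST2 at 2.79, 1.45 and 1.96, and COL1A2 was listed at 0 throughout. CD68, a lysosomal protein gene, was the only blood and immune marker tested, at 6.41, 7.33 and 8.0 FPKM, and PTPRC and HBB were listed at 0. Of the squamous and cervical carcinoma markers, KRT17 was at 5.50, 7.28 and 12.9 FPKM, SFN at 7.79, 3.39 and 9.05 and CD44 at 1.89, 2.05 and 1.12, and KRT5 and KRT14 were listed at 0 (median log2 change of the 3 tested -0.19, mean 0.04, camera direction up, adjusted p = 0.759). No member of these 4 lists passed over all genes or adjusted over the list alone.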

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

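With 1 control library and 2 clones, leaving out a clone leaves no test, so counts of calls have no value there; the KANK1 log2 change lay between -0.31 and -0.25 without either clone. No paired analysis was possible because the control has 1 library. KANK1 was not called under any of 8 alternatives with a test, with log2 changes from -0.34 to -0.16. Leaving out duplicate symbols removed no gene. The causes of the changes below were not tested, except that a stricter filter tests fewer genes and a lower pseudocount widens the changes of low genes. Genes listed at 0, the same sum and the chromosome subtraction were chosen after the data were seen.

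Calls lower in the clones, 6 as reported, numbered 0 with a pseudocount of 0.1 and 0 with no filter (486 genes at an unadjusted p under 0.05 by limma). They numbered 2 without genes listed at 0, 3 with FPKM scaled to the same sum and 3 after the chromosome subtraction. Calls higher, 4 as reported, numbered 0 with no filter and 9 at a mean of at least 5 FPKM, where SPARC and EPCAM passed, and EGR1 passed as lower. Without genes listed at 0, EGR1 passed as lower and HSPB8 as higher. Scaling to the same sum moved the median of all genes to 0.11. Of the 10 called genes, 7 kept the call under quantile normalization, 8 at a mean of at least 5 FPKM and 8 without a trend. With FPKM scaled to the same sum 6 kept it, and 6 after the chromosome subtraction. Only 3 kept it with a pseudocount of 0.1, 3 without genes listed at 0 and 0 with no filter. Called lists, 8 as reported, numbered 4 under quantile normalization, 6 at a mean of at least 5 FPKM and 9 after the chromosome subtraction, which added G1/S. They numbered 0 with an estimated correlation, where 1 degree of freedom leaves hardly any power. No list was called by fry either (lowest fry adjusted p = 0.801). The median of the common reference genes turned to 0.043 under quantile normalization.

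Genes at least 2-fold apart numbered 683 for clone 114, 761 for clone 174 and 1177 between the clones with a pseudocount of 0.1, and 197, 204 and 361 at a mean of at least 5 FPKM, against 396, 447 and 726. The covariance was 0.0997 with a pseudocount of 0.1 (0.0569 as reported). Unchanged clones sharing a control that varies as much as a clone would give 0.339 (0.172 as reported).

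Of the chromosome medians, 73 values stayed within the interval of the reported median. With a pseudocount of 0.1, clone 114 gave -0.44 for chromosome 5 and 0.42 for chromosome 7, and clone 174 gave 0.27 for chromosome 2, -0.20 for 3, -0.27 for 7, -0.52 for 14 and -0.26 for 22. At a mean of at least 5 FPKM, clone 114 gave -0.078 for chromosome 1, -0.0086 for 2, -0.23 for 4, -0.44 for 5, 0.049 for 8, -0.061 for 9, 0.029 for 11, -0.23 for 15, -0.22 for 17 and -0.15 for 22. Clone 174 gave -0.26 for chromosome 22, and chromosome 19 turned from 0.024 to -0.031.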

Other observations

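In the tests below, the chromosome subtraction, the removal of 2 members in a list's direction and the count of control libraries were chosen after these or closely related results had been seen. Within chromosomes the changes formed blocks of neighbouring genes. In clone 114 the running median over 61 genes reached -0.80 at the start of chromosome 5, from SDHA to UGT3A2, where 98.4% of genes were lower than in the control, and -0.54 at the end of chromosome 17, from CBX2 to RAB40B. The same clone had 0.40 on chromosome 16 from ZFP90 to WWOX and 0.45 on chromosome 19 from PGPEP1 to ZNF675. Clone 174 reached 0.51 on chromosome 1 from NENF to ZNF678, 0.44 on chromosome 6 from STMND1 to ZSCAN26 and -0.48 on chromosome 5 from NUP155 to IPO11. Windows beyond the highest value of 100 shuffles made up 19.3% of all in clone 114 and 14.5% in clone 174. Around KANK1, 13 tested neighbours from WASH1 to AK3 had a median log2 change of 0.26 in clone 114 (8 higher, range -0.45 to 0.85) and -0.27 in clone 174 (5 higher, range -0.78 to 0.68), so they did not move together, and DOCK8, the gene next to KANK1, was at 1.09 FPKM in the control, 2.79 in clone 114 and 2.34 in clone 174.

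For the shift of chromosome 7 genes in clone 114, removing the trend with expression, GC content and transcript length left their median at 0.40 (0.37 to 0.43), which argues against that trend. The shift was spread over most genes, with 87.6% of the chromosome 7 genes higher than in the control (exact 95% interval 84.7% to 90.2%). A few genes with large changes can hardly move a median, so this share was no separate test of that explanation. A difference in chromosome copy number between the libraries predicts a shift in the same direction at every expression level. The medians of 4 groups of genes from low to high expression were 0.40, 0.43, 0.41 and 0.30 (0.21 to 0.35 for the last), so the most expressed genes shifted less. Copy number may be a candidate explanation, and abundant genes of all chromosomes were lower in this clone (median -0.24 in the 1258 most abundant); DNA was not analysed here, and whether such a difference arose in the clone or already varied among the control cells stays open.

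The changes of the cholesterol, immediate early, p53 and extracellular matrix lists had the same direction of the median in both clones, although 14 of 29 extracellular matrix genes went opposite ways. Shifts of whole-chromosome medians alone do not account for them, since all 4 lists kept an adjusted p under 0.05 by camera after the subtraction. The subtraction left shifts of blocks within chromosomes in place, so it cannot exclude those as a source. The 4 lists also kept the call without the 2 members of largest change in the list's direction, so 1 or 2 members do not carry the calls. By camera, the immediate early list then had adjusted p = 0.0109. The extracellular matrix list, without SPARC and MMP2, had adjusted p = 0.00555. The state of the single control library and the editing of KANK1 cannot be told apart, because there is 1 control library and it enters every comparison. Transfection, Cas9 and the cloning of cells, which both clones share, cannot be told apart from the loss of KANK1 either. The labels give days after the vector only for the clones. All 4 calls were made by camera with the preset correlation, and fry made none of them (fry adjusted p = 0.801 for each). With an estimated correlation camera has 1 degree of freedom and can hardly call a list, so its adjusted p of 0.787 cannot decide whether they hold. The estimated correlations lay between -0.028 for cholesterol synthesis and 0.051 for immediate early genes.

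Small RNA genes made up 7 of the 10 calls, in libraries selected for poly(A) tails, so their values may not stand for levels of the mature small RNAs. Short transcripts estimated at 0 by the authors' processing are a candidate source: 80.8% of the 26 tested small nucleolar and Cajal body RNA genes were listed at 0 in at least 1 library, against 0.280% of protein-coding genes. A change of the host gene is argued against, since the host genes of 6 of the 7 called small RNA genes (SCARNA22 had none matched) changed by a median of -0.13 in the direction of the small RNA (range -0.66 to 0.39). RPL10, the host of SNORA70, was at 499 FPKM in the control and 317 and 313 in the clones. The small RNA genes also separated the clones, with 16 of 26 at least 2-fold apart between them. Some had equal values within a library: SNORD22 and SCARNA27 were both at 29.872 FPKM in clone 114. SNORD94 and SNORA34 were both at 14.9411 FPKM in clone 174. Such equal values may stand for few fragments, whose number was not estimated here.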
